A study of Mus musculus with 9 samples.

How the data were processed

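RNA-seq was carried out on C2C12 mouse myotubes infected with adenovirus for LacZ, full-length PGC-1α (FL) or PGC-1α without its C-terminal domain (dCTD), with 3 libraries per virus, described in the labels as biological replicates. Libraries were prepared from polyadenylated RNA with a stranded mRNA kit, per the labels' protocols. The design text also describes an in vitro RNA-binding assay, which was not analysed here. The submitters' processing notes name Trim Galore 0.4.3.1, FastQC 0.72, STAR 2.7.2b, featureCounts 1.6.4 and DESeq2 2.11.40.6 with the genome build mm10, without settings, so the strand setting of the counting is not known. Reads of overlapping genes on either strand, and of near-identical genes such as ribosomal protein genes and their pseudogenes, the myosin heavy chain genes and the Serpinb6 family, may have been divided or dropped in counting, so values of those genes are uncertain to that extent.

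The authors deposited 2 tables of 55421 genes, 1 with the FL and LacZ libraries and 1 with the dCTD and LacZ libraries. The deposited values per library are a signal headed as normalized counts, per the file headers, in which whole read counts have been divided by a size factor. In every library all values above 0 were whole multiples of the smallest one, so the whole reads were recovered for 100% of 317312 values within a tolerance of 0.001 reads, and the reads of the LacZ libraries differed at 0 genes between the tables. The authors' log2 fold changes with standard errors, and the authors' p-values with adjusted p-values, stand in the same tables, per the file headers. They were used only for the counts credited to the authors' deposited table. In 14 cases a gene name had been turned into a date and was restored from the gene's identifier. Positions are those of the deposited tables, in mm10, counted from 1.

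FL and LacZ, and dCTD and LacZ, were compared within their own table with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (trend) and are robust to outlying genes, on log2(value + 1), for genes with a mean of at least 10. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. FL and dCTD stand in tables that were normalized separately. They were compared with the same test on the recovered reads after the 9 libraries had been scaled together by median-of-ratios size factors. The design written before the data were examined had foreseen 1 fit over all 9 libraries and no test across tables, so these choices were made after seeing the files. Gene lists, comparisons, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Fold changes on this scale understate the change of genes with low counts. Where a group had 0 counts, a lower bound was computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% exact counting interval. Intervals and floors cover counting error only, since reads are not independent molecules.

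For 37 gene lists, 36 with at least 5 tested members, the members that rose and fell were counted and camera in limma was run with a preset correlation between genes of 0.01 and with a correlation estimated for each list. The list of mitochondrially encoded genes had no member to test. With the estimated correlation 0 lists passed in any comparison by camera, where 3, 13 and 4 lists had an unadjusted p under 0.05 for FL against LacZ, dCTD against LacZ and FL against dCTD, and 23, 21 and 20 lists passed with the preset correlation. The preset test also passes lists in splits that mix the groups, where part of the difference between viruses remains between the sides. Whether a list passed depended on the correlation used, so lists are described by the count of their members, each tested on its own. Members of a list can move together, so that count is no test of the list. Of all tested genes, 59.2% passed for FL against LacZ, 44.8% for dCTD against LacZ and 38.9% for FL against dCTD. Counts of members near these shares do not set a list apart.

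Genes named are Ppargc1a, for each comparison the 6 highest and the 6 lowest log2 fold changes among genes past the threshold, with a mean of at least 50, a regular symbol and all libraries of 1 group above all of the other, and for each list up to 3 members with the smallest p for FL against LacZ and up to 2 for FL against dCTD. Genes named outside this rule are said to be. Of the 163 gene values in the text that passed the test, 161 had all 3 libraries of 1 group above all 3 of the other, the exceptions being Pcx and Pcna for FL against LacZ. The rule itself asks for this of the highest and lowest genes and picks list members by p, so the count is no test.

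The same steps were tested on simulated data, with counts drawn for 18829 genes from the means and library sizes of the real libraries. A small set of genes was changed by known folds, up or down, with 47 to 50 tested genes at each fold. For FL against LacZ limma called 72.0% of genes changed 1.25-fold, 80.0% at 1.5-fold, 89.6% at 2-fold and 98.0% at 4-fold, and 11 of 179 calls (6.15%) were false. For dCTD against LacZ it called 70.0%, 80.0%, 85.7% and 100%, with 14 of 178 calls (7.87%) false, and for FL against dCTD 64.0%, 82.0%, 90.0% and 100%, with 9 of 176 (5.11%) false. Far fewer genes were changed than passed in the real data (10799, 8094 and 7059), so these rates do not carry over to the real comparisons. Nor was the scaling tested with so many genes changed. Genes were drawn independently of each other, while complex I subunits had an estimated correlation of 0.58 for FL against LacZ. The simulation therefore does not show how the list tests behave when members move together. A list raised 1.25-fold was called in each comparison with either correlation. Of the other lists, 1 was called falsely for dCTD against LacZ with the preset correlation, and 0 in the other comparisons or with the estimated correlation.

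Replicates of a group differed by more than counting error in every pair (chi-square per degree of freedom 5.50 to 15.3), so no library appeared to be deposited more than once. The share of counts taken by the 10 highest genes was 5.89% with LacZ, 5.24% with FL and 4.93% with dCTD. The labels number the replicates and give no shared day or batch, and the numbers were not used to pair libraries. Alternatives were the pseudocount, the filter on low values, total-count scaling with and without Ppargc1a, a replicate block, a minimum change, leaving out each library, and, on the recovered reads, edgeR 4.0.16 with TMM or RLE factors, limma-voom and DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.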

Results

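The data were RNA-seq profiles of C2C12 myotubes, muscle fibres formed in culture by fusion of a mouse myoblast line. The cells had differentiated for 4 days and were then exposed for 4 h to an adenovirus at 3 infectious particles per cell. RNA was taken 48 h after infection, and 9 libraries were made, 3 for each of 3 viruses. The first virus carried LacZ, a bacterial enzyme used as the control. The second carried full-length PGC-1α, here FL, a transcriptional coactivator that drives mitochondrial gene expression. The third carried PGC-1α lacking its C-terminal domain, here dCTD, the end of the protein that holds its RNA-binding motifs. FL was compared with LacZ for the response to the intact coactivator, and dCTD with LacZ for the response that remained without the domain. FL was compared with dCTD for the difference between these forms, which may include a difference in transgene level. Any other difference between the viruses also goes with the group and was not tested. Depth was 110309704 to 118931863 counts per library with LacZ, 99906750 to 123446198 with FL and 87090490 to 110673140 with dCTD, and 25707 to 26957 genes had at least 1 count. All 37 genes of the mitochondrial chromosome were listed at 0 in all 9 libraries, so every mitochondrial gene described here is encoded in the nucleus. A value after a gene name is its log2 fold change ± its standard error from limma, with 3 libraries per group, on the scale log2(normalized count + 1).

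Ppargc1a, the gene for PGC-1α (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726 in mm10), was read first in every library, since it shows whether the PGC-1α transcript was raised in each culture. Its normalized count was 397 ± 13.0 (SD, n = 3) with LacZ, 211489 ± 14759 (n = 3) with FL and 112756 ± 10934 (n = 3) with dCTD, on a scale shared by all libraries. These levels were 533-fold and 284-fold that with LacZ. The FL level was 1.88 times the dCTD level, a log2 difference of 0.91 ± 0.07 (limma, adjusted p = 1.7e-07), with all 3 FL libraries above all 3 dCTD libraries. The counts did not separate the transgene from the cell's own gene or FL from dCTD, and the deletion shortens the transcript that can be counted by a length not given in the sources used here. How much of the ratio comes from the shorter transcript was not tested, so the transgene levels of FL and dCTD may have differed by less than the counts do. PGC-1α protein is not part of these data, so the relative amounts of the FL and dCTD proteins are not known.

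**Figure D1:**
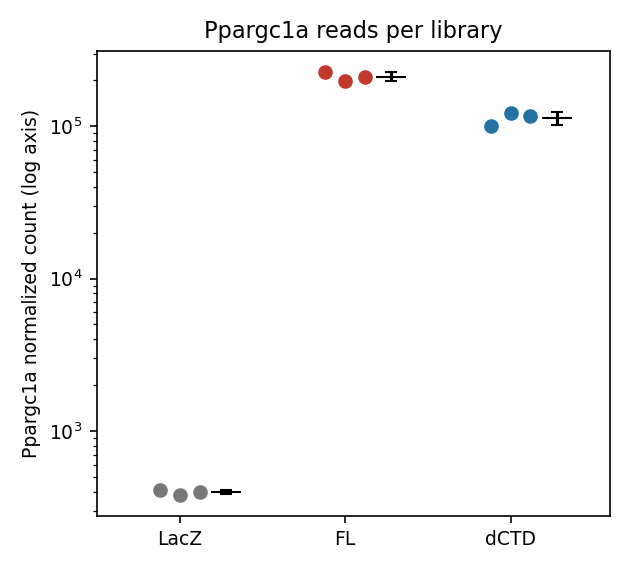
Normalized count of Ppargc1a in each of the 9 libraries (points, log axis) by virus, with the mean and SD of each group of 3 beside the points. The LacZ libraries lie near 397, the dCTD libraries near 112756 and the FL libraries near 211489.

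With FL, genes of the mitochondrial energy pathways rose together over LacZ. All 37 tested subunits of complex I, the NADH dehydrogenase, rose, with a median log2 fold change of 1.30. The same held for all 13 subunits of complexes II and III (median 1.53), all 15 of complex IV with cytochrome c (1.20) and all 15 of ATP synthase (1.38). Among them, Cycs, the cytochrome c of somatic tissues, rose by 2.94 ± 0.04, the complex IV subunit Cox7a1 by 3.95 ± 0.05, the ATP synthase subunit Atp5g1 by 2.59 ± 0.04, the complex III subunit Cyc1 by 2.17 ± 0.04 and the complex I subunit Ndufb10 by 2.30 ± 0.04. In the TCA cycle list 22 of 23 genes rose (median 1.5), including Idh3a (2.82 ± 0.04) and Cs, which encodes citrate synthase (2.62 ± 0.04), and 1 fell, Pcx, which encodes pyruvate carboxylase (-0.10). The Pcx call was lost without LacZ replicate 2 (adjusted p = 0.231, limma), FL replicate 1 (0.107) or FL replicate 3 (0.126). It was also lost with no filter on low values (0.0575), with all 9 libraries scaled together (0.0502) and with DESeq2 (0.0848). All 47 genes of the mitochondrial ribosome rose (median 0.81), led by Mrpl47 (2.26 ± 0.04), as did 24 of 25 genes of mitochondrial import, DNA upkeep and dynamics (median 1.0), among them Twnk, the mitochondrial DNA helicase (1.97 ± 0.04), and the chaperonin gene Hspd1 (1.91 ± 0.04). The camera test with a preset correlation of 0.01 between genes gave these 7 lists adjusted p-values from 3.6e-22 to 4.6e-12, and each had an adjusted p = 0.197 with an estimated correlation.

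Genes for fuel use rose with FL as well. Of 28 genes of fatty acid uptake and oxidation, 26 rose and 0 fell (median 1.03, camera adjusted p = 3.3e-15, and adjusted p = 0.197 with an estimated correlation). The fatty acid carrier Fabp3 rose by 3.01 ± 0.04, the thioesterase Acot13 by 2.45 ± 0.04 and Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, by 2.22 ± 0.04. Of 19 genes of ketone and branched-chain amino acid catabolism 14 rose and 0 fell (median 0.33, adjusted p = 2.5e-06, 0.28 with an estimated correlation), with Oxct1, an enzyme of ketone use, at 2.34 ± 0.04. In glycolysis and lactate handling 18 of 25 genes rose and 4 fell (median 0.41, adjusted p = 0.00012, 0.424 with an estimated correlation). The lactate dehydrogenase subunit Ldhb (4.61 ± 0.05) and the hexokinase Hk1 (2.14 ± 0.04) were higher and the muscle phosphoglycerate mutase Pgam2 was lower (-0.77 ± 0.04). Of 20 antioxidant and NRF2 target genes 15 rose and 4 fell (median 0.42, adjusted p = 0.00051, 0.28 with an estimated correlation), with the mitochondrial superoxide dismutase Sod2 at 2.28 ± 0.04. Lipogenesis and sterol synthesis moved both ways, with 5 of 20 genes up and 7 down (adjusted p = 0.584), for example Elovl6 (0.43 ± 0.05) and Dhcr7 (-0.58 ± 0.04).

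Of 26 tested genes listed beforehand as PGC-1α targets in muscle, 20 rose and 3 fell with FL (median 1.29, adjusted p = 6.9e-11, 0.197 with an estimated correlation). The mitochondrial creatine kinase Ckmt2 rose by 5.24 ± 0.05, the glucose transporter Slc2a4 by 4.34 ± 0.06 and Pdk4, a kinase that restrains pyruvate dehydrogenase, by 2.74 ± 0.04. In the list of nuclear receptors and the PGC-1 network 11 of 27 genes rose and 9 fell. Its median was -0.01, its mean and its test pointed up, and its adjusted p was 0.584. Perm1, a regulator of muscle oxidative genes, rose by 7.58 ± 0.07, the fatty acid sensor Ppara by 3.64 ± 0.12 and Sirt3, a mitochondrial deacetylase, by 1.93 ± 0.05, while the muscle transcription factor Mef2c fell (-1.29 ± 0.04). Angiogenic factors rose in 9 of 15 cases and fell in 1 (median 0.23, adjusted p = 0.0162, 0.197 with an estimated correlation), with Vegfb at 1.73 ± 0.05 and Vegfa at 0.97 ± 0.04.

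The genes with the largest rises over LacZ were nearly silent in the control. Lcn2, a secreted siderophore-binding protein (chromosome 2, 32384633 to 32388252), had 1 count over the 3 LacZ libraries and 19708 over the 3 FL libraries, a ratio of 22226 with a 95% counting interval from 3989 to 877909. Nr0b2, a nuclear receptor that represses others, and the kinase gene Sgk2 had 0 counts with LacZ and were at least 1409-fold and at least 641-fold higher with FL, against a floor of 3 counts over the group. Bcan, a proteoglycan gene, had 3 counts with LacZ and a ratio of 1141 (interval 390 to 5535). The matrix gene Tnxb rose by 10.03 ± 0.23 and Cidea, which encodes a lipid droplet protein, by 9.56 ± 0.76. The lowest values were those of the chemokine receptor Ccr9 (-4.29 ± 0.33), Lrrc26 (-4.13 ± 0.17), the lipid droplet enzyme Hsd17b13 (-3.98 ± 0.09), the transcription factor Grhl3 (-3.34 ± 0.08), Rnase6 (-3.21 ± 0.19) and Galnt5 (-3.21 ± 0.18).

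Genes of the contractile apparatus and of excitation were lower with FL. Among fast sarcomere genes 13 of 16 fell and 2 rose (median -0.86, adjusted p = 3.3e-07, 0.197 with an estimated correlation). They included the fast myosin Myh1 (-1.14 ± 0.04), the calcium pump Atp2a1 (-1.12 ± 0.04) and Actn3 (-0.94 ± 0.04). Among slow sarcomere genes 9 of 12 also fell and 2 rose (median -0.54, adjusted p = 0.0045, 0.274 with an estimated correlation), with Csrp3 at -1.85 ± 0.04 and the slow myosin Myh7 at -1.16 ± 0.04, against a rise of the tropomyosin Tpm3 (1.71 ± 0.04). Developmental sarcomere and differentiation genes fell in 18 of 22 cases and rose in 2 (median -0.75, adjusted p = 5.5e-09, 0.178 with an estimated correlation), among them the embryonic myosin Myh3 (-1.68 ± 0.04) and Actc1 (-1.33 ± 0.04). Calcium handling and excitation genes fell in 14 of 18 cases and rose in 2 (median -1.0, adjusted p = 4.5e-07, 0.197 with an estimated correlation), with the sodium channel Scn4a at -1.82 ± 0.05 and Stac3 at -1.54 ± 0.04, while Pln, which encodes the calcium pump inhibitor phospholamban, rose by 5.34 ± 0.21. Of 17 neuromuscular junction genes 12 fell and 3 rose (median -0.59, adjusted p = 9.5e-05, 0.197 with an estimated correlation). The fetal acetylcholine receptor subunit Chrng fell (-1.72 ± 0.04) and Dok7, an activator of the junction's receptor kinase, rose (1.24 ± 0.04).

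Interferon response, stress and cell cycle genes were higher with FL than with LacZ. In the interferon list 17 of 21 genes rose and 1 fell (median 1.01, adjusted p = 5.8e-06, 0.231 with an estimated correlation). Ifi44 rose by 3.00 ± 0.13, Oasl2 by 2.71 ± 0.08 and the ubiquitin-like modifier Isg15 by 1.43 ± 0.07, and the gene that fell was Mx1 (-2.63). In the integrated stress response 17 of 22 genes rose and 1 fell (median 0.57, adjusted p = 1.2e-05, 0.380 with an estimated correlation), with the stress cytokine Gdf15 at 2.42 ± 0.09, Shmt2 at 0.95 ± 0.04 and the transcription factor Atf4 at 0.69 ± 0.04. The gene of that list that fell was Fgf21, a stress-induced hormone (-1.01). Of 18 proliferating cell markers 15 rose and 2, E2f1 (-0.30) and Pcna (-0.13), fell (median 0.54, adjusted p = 0.00043, 0.380 with an estimated correlation), with the ribonucleotide reductase subunit Rrm2 at 1.29 ± 0.04 and Birc5 at 0.90 ± 0.07. The Pcna call was lost without LacZ replicate 3 (adjusted p = 0.125, limma) or FL replicate 1 (0.0866). The lists of NF-kB and inflammatory genes (8 of 20 up, 3 down, adjusted p = 0.525), p53 and apoptosis (7 of 18 up, 8 down, 0.569) and atrophy and proteolysis (8 of 17 up, 4 down, 0.406) did not pass the list test. Their members included Nfkb2 (0.35 ± 0.04), the cell cycle inhibitor Cdkn1a (-0.78 ± 0.04) and the ubiquitin ligase Trim63 (-1.34 ± 0.04). Pcx, Mx1, Fgf21, E2f1 and Pcna were named after their values were seen, being the exceptions in their lists.

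Markers of other cell types or states were also compared between FL and LacZ. Myoblast and reserve cell markers rose in 7 of 16 cases and fell in 3 (adjusted p = 0.337), with Myf5 at 0.80 ± 0.05 and Itga7 at -0.60 ± 0.04. Adipocyte markers rose in 5 of 7 cases (median 0.80, adjusted p = 0.0024, 0.274 with an estimated correlation), among them Pnpla2, a triglyceride lipase that muscle also expresses (2.92 ± 0.04), and the lipid droplet gene Cidec, which had 1 count over the LacZ libraries and 1072 over the FL libraries, a ratio of 1209 (interval 217 to 47795). Brown adipocyte markers rose in 7 of 10 cases and fell in 2 (median 0.59, adjusted p = 0.0217, 0.197 with an estimated correlation), and the genes that moved most were Cidea, Ppara and the glycerol kinase Gk (2.50 ± 0.05), which are metabolic genes also used outside fat. Fibroblast markers (2 of 10 up, 3 down), macrophage markers (1 of 6 up, 2 down), endothelial markers (0 of 7 up, 3 down) and osteoblast markers (3 of 7 up, 1 down) did not pass the list test, with adjusted p-values of 0.569, 0.584, 0.531 and 0.569. The fibroblast list had a median of -0.05 and a mean of 0.08. Extracellular matrix and TGF-beta genes (4 of 24 up, 7 down, 0.569), splicing and nuclear RNA-binding factors (10 of 29 up, 5 down, 0.702) and the cytosolic ribosome (2 of 37 up, 11 down, 0.153) did not pass it either. The cytosolic ribosome passed it, with a median of -0.11 and adjusted p = 0.0076, when libraries were scaled by their total count without Ppargc1a, and with adjusted p = 0.0445 without LacZ replicate 1.

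In all, 10799 of 18227 tested genes differed between FL and LacZ by limma at an adjusted p of 0.05, 5637 higher and 5162 lower with FL, and of these 1576 and 801 changed at least 2-fold. With libraries scaled by their total count without Ppargc1a, 4586 were higher and 7145 lower, so the balance of small changes depended on the scaling. At a minimum change of 1.5-fold, 2679 genes passed. The authors' deposited table lists 10098 genes at an adjusted p of 0.05, 5426 higher and 4672 lower, of which 9656 were among the limma calls, all with the same sign. Adjusted over the list alone, the counts of members up and down became 15 and 0 for ketone and branched-chain amino acid catabolism, 11 and 10 for nuclear receptors, 21 and 4 for PGC-1α targets, 7 and 7 for lipogenesis, 2 and 14 for fast sarcomere, 2 and 19 for developmental sarcomere, 10 and 1 for angiogenic factors, 10 and 3 for splicing, 1 and 9 for the cytosolic ribosome and 2 and 2 for macrophage markers. The other lists kept their counts.

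With dCTD the mitochondrial genes also rose over LacZ, with smaller medians than with FL. All 37 subunits of complex I rose (median 0.89), as did all 13 of complexes II and III (1.22), all 15 of complex IV with cytochrome c (0.93), all 15 of ATP synthase (1.04), 22 of 23 TCA cycle genes (1.07), 44 of 47 mitochondrial ribosome genes (0.66) and all 25 genes of mitochondrial import, DNA upkeep and dynamics (0.71), and 0 of these genes fell. Cycs rose by 2.14 ± 0.04, Idh3a by 2.06 ± 0.04, Cs by 1.38 ± 0.04 and Cox7a1 by 3.78 ± 0.07. Camera gave these lists adjusted p-values from 3.4e-28 to 1.1e-15, and 0.125 or 0.129 with an estimated correlation. Fatty acid uptake and oxidation genes rose in 25 of 28 cases (median 0.69, 0.125 with an estimated correlation), with Fabp3 at 2.18 ± 0.05. Ketone and branched-chain amino acid genes rose in 18 of 19 cases (median 0.36, 0.125), known PGC-1α targets in 20 of 26 with 1 lower (0.93, 0.125), angiogenic factors in 10 of 15 (0.30, 0.125), glycolysis and lactate genes in 19 of 25 with 2 lower (0.28, 0.278) and antioxidant genes in 13 of 20 with 2 lower (0.16, 0.149), where the last value of each bracket is the adjusted p with an estimated correlation and each list passed with the preset one. Perm1 rose by 6.57 ± 0.08, Ckmt2 by 5.67 ± 0.05, Slc2a4 by 2.81 ± 0.07 and Pdk4 by 1.43 ± 0.04.

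Beside Ppargc1a, the highest values with dCTD belonged in part to genes other than those highest with FL, though these genes rose with FL too. Tmprss13, a membrane serine protease gene with 0 counts in the LacZ libraries, was at least 322-fold higher with dCTD and at least 66.9-fold with FL. Lrcol1 had 3 counts with LacZ and a ratio of 299 with dCTD (interval 102 to 1451) and 339 with FL (interval 116 to 1645). The mitochondrial creatine kinase Ckmt1 rose by 7.45 ± 0.18, beside 8.15 ± 0.16 with FL. Tnxb rose by 7.10 ± 0.27 and Pln by 7.08 ± 0.19. The lowest were Hsd17b13 (-4.20 ± 0.12), Lrrc26 (-3.99 ± 0.22), Ccr9 (-2.94 ± 0.15), Smim6 (-2.93 ± 0.12), the growth factor Gdf5 (-2.90 ± 0.08) and the protease Asprv1 (-2.70 ± 0.14).

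Part of the lists of muscle genes were lower with dCTD than with LacZ. Fast sarcomere genes fell in 11 of 16 cases and rose in 1 (median -0.35, camera adjusted p = 4.1e-05, 0.297 with an estimated correlation), developmental sarcomere and differentiation genes fell in 16 of 22 and rose in 4 (-0.51, 2.3e-07, 0.125), calcium handling genes fell in 11 of 18 and rose in 4 (-0.42, 0.00020, 0.164) and neuromuscular junction genes fell in 11 of 17 and rose in 4 (-0.29, 0.00028, 0.207), each bracket in the same order. Myh3 was at -1.79 ± 0.04, beside -1.68 ± 0.04 with FL, and Myh1 at -0.28 ± 0.04, beside -1.14 ± 0.04 with FL. Slow sarcomere genes moved both ways, 4 of 12 up and 5 down (adjusted p = 0.569), with Myh7 at -0.75 ± 0.05 and Myh7b at 0.43 ± 0.06. The interferon list had 2 of 21 genes up and 4 down (median -0.13, adjusted p = 0.370), the integrated stress response 5 of 22 up and 6 down (0.01, 0.817) and the proliferating cell markers 3 of 18 up and 3 down (0.05, 0.982), and the test of these last lists pointed down although their medians and means lay above 0. Oasl2 was at 0.54 ± 0.10 and Gdf15 at 0.53 ± 0.11, both past the test, while Ifi44 (-0.18 ± 0.21), Isg15 (-0.13 ± 0.08) and Atf4 (0.05 ± 0.04) did not pass it. Atf4 did without LacZ replicate 1 (adjusted p = 0.0445, limma). Extracellular matrix and TGF-beta genes were lower in 13 of 24 cases and higher in 3 (median -0.12, adjusted p = 0.0086, 0.278 with an estimated correlation). The cytosolic ribosome was lower in 15 of 37 cases (median -0.10, adjusted p = 0.0043, 0.783 with an estimated correlation), a call that was lost without dCTD replicate 2 (adjusted p = 0.0731).

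Adipocyte markers rose with dCTD in 4 of 6 cases (median 0.48, camera adjusted p = 0.0116, 0.129 with an estimated correlation) and brown adipocyte markers in 7 of 10 with 2 lower (0.78, 0.0067, 0.125). Pnpla2 was at 1.07 ± 0.04 and Cidea at 6.19 ± 0.60. The p53 and apoptosis list did not pass (4 of 18 up, 7 down, adjusted p = 0.0792). It did without LacZ replicate 1 (0.0438) and with no filter on low values (0.0257). In total 8094 of 18066 tested genes differed between dCTD and LacZ by limma, 4172 higher and 3922 lower, with 776 and 480 of them at least 2-fold, and 1398 genes passed at a minimum change of 1.5-fold. The authors' deposited table lists 7370 genes, 3826 higher and 3544 lower, of which 7178 were among the limma calls, all with the same sign. Adjusted over the list alone, the counts up and down became 22 and 1 for the TCA cycle, 26 and 0 for fatty acid genes, 20 and 2 for PGC-1α targets, 4 and 6 for slow sarcomere, 4 and 8 for p53 and apoptosis, 14 and 2 for antioxidant genes, 3 and 16 for extracellular matrix and 1 and 3 for proliferating cell markers. They became 10 and 10 for nuclear receptors, 4 and 1 for splicing and 0 and 1 for macrophage markers. The other lists kept their counts.

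**Figure D2:**
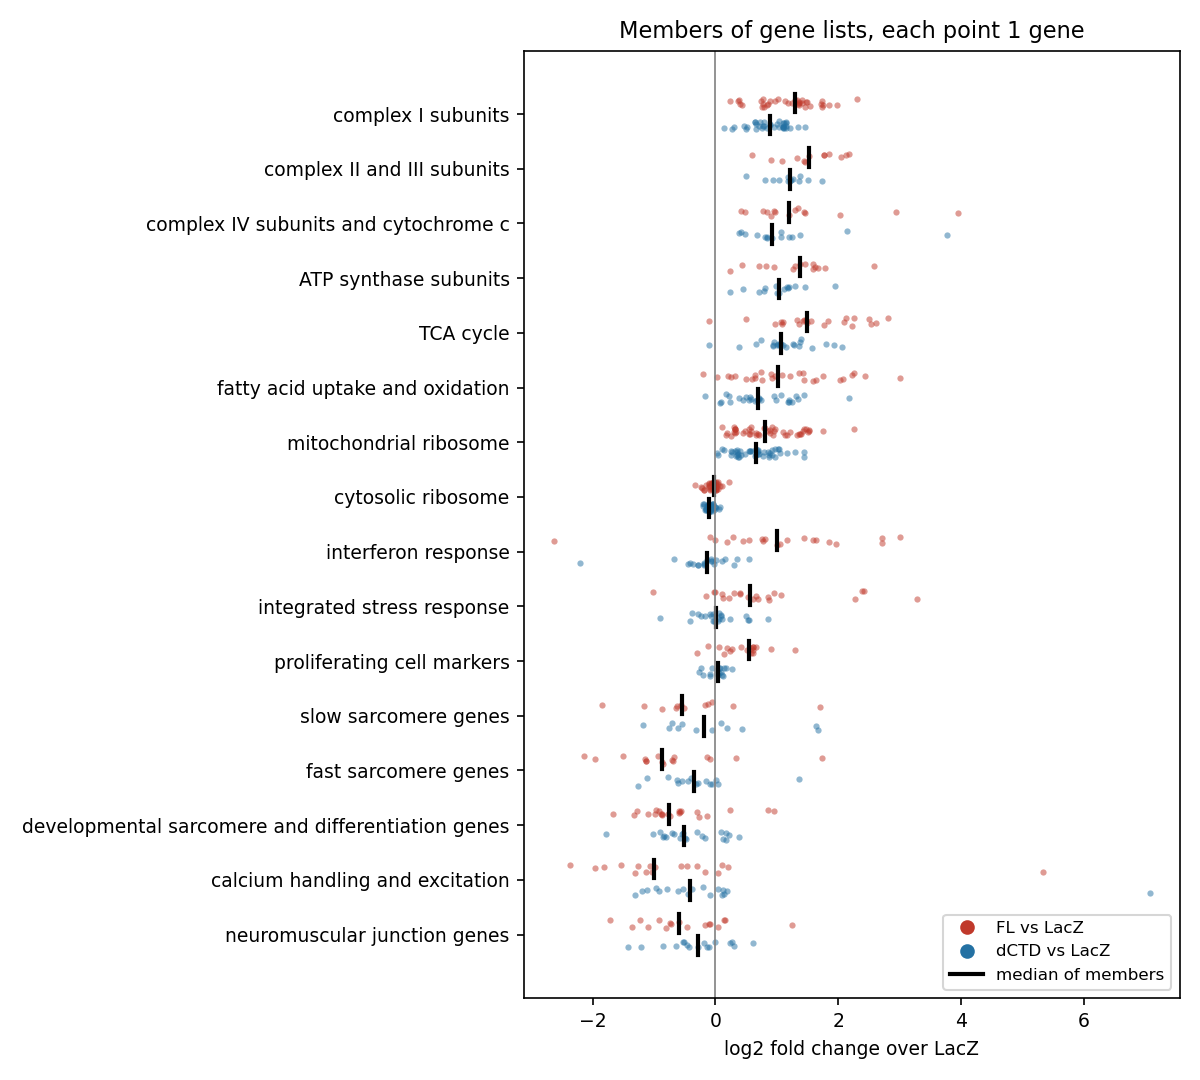
Log2 fold change over LacZ (horizontal axis) of each member (points) of 16 gene lists with FL and with dCTD, with the median of each list as a black bar. The complex I medians are 1.30 with FL and 0.89 with dCTD, and the interferon medians are 1.01 and -0.13.

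FL and dCTD were then compared with each other on counts scaled together. Interferon response genes had the largest median difference of the 36 lists. Of 20 tested, 18 were higher with FL and 0 lower (median 0.98, camera adjusted p = 4.2e-13, 0.194 with an estimated correlation), with Ifi44 at 3.17 ± 0.15, Oasl2 at 2.16 ± 0.08 and Isg15 at 1.56 ± 0.07. The integrated stress response was higher with FL in 20 of 22 cases and lower in 0 (median 0.57, 4.2e-13, 0.290), with Gdf15 at 1.88 ± 0.11, Shmt2 at 0.71 ± 0.04 and Atf4 at 0.63 ± 0.04. Proliferating cell markers were higher in 14 of 18 cases and lower in 0 (median 0.48, 6.1e-08, 0.290), with Rrm2 at 1.01 ± 0.04 and Cenpf at 0.65 ± 0.04. Of 16 myoblast and reserve cell markers 4 were higher and 3 lower (median -0.01, mean 0.01, adjusted p = 0.979). Sdc4 was at 0.39 ± 0.04 and Met at 0.26 ± 0.04.

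Most lists of mitochondrial and fuel genes were higher with FL than with dCTD by smaller steps. The TCA cycle had the smallest list p, with 22 of 23 genes higher (median 0.40, camera adjusted p = 3.4e-14, 0.290 with an estimated correlation), including Cs (1.23 ± 0.04) and Mdh2 (0.98 ± 0.04). Higher with FL were also 27 of 37 complex I subunits with 1 lower (median 0.29), 11 of 13 of complexes II and III (0.34), 8 of 15 of complex IV with cytochrome c (0.16), 11 of 15 of ATP synthase with 1 lower (0.26), 32 of 47 of the mitochondrial ribosome with 2 lower (0.19), 22 of 25 of mitochondrial import with 2 lower (0.38), 19 of 28 of fatty acid uptake and oxidation with 3 lower (0.42) and 16 of 26 known PGC-1α targets with 4 lower (0.41). These 8 lists passed with the preset correlation, the largest adjusted p being 0.00039, and had adjusted p-values from 0.290 to 0.409 with an estimated correlation. Ketone and branched-chain amino acid genes did not pass the list test, with 6 of 19 higher and 7 lower (median 0.04, adjusted p = 0.367). Acot2, a mitochondrial thioesterase, differed by 1.74 ± 0.05, Slc2a4 by 1.51 ± 0.06, Ldhb by 1.36 ± 0.05, Pdk4 by 1.30 ± 0.04 and Ppara by 2.37 ± 0.13. Ckmt2 was lower with FL (-0.44 ± 0.05). Cox7a1 did not pass the test (0.16 ± 0.07, adjusted p = 0.0783, limma). It did without dCTD replicate 3 (0.24, adjusted p = 0.0010), in a fit of the FL and dCTD libraries alone (0.0229) and with DESeq2 (0.0212).

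The lists of sarcomere, calcium handling and neuromuscular junction genes were lower with FL than with dCTD, with exceptions among their members. Calcium handling and excitation genes were lower in 13 of 18 cases and higher in 0 (median -0.39, camera adjusted p = 8.3e-10, 0.194 with an estimated correlation), with Trdn, a protein of the calcium release complex, at -1.10 ± 0.05. Fast sarcomere genes were lower in 12 of 16 cases (-0.35, 3.3e-07, 0.297), slow sarcomere genes in 8 of 12 (-0.35, 0.00011, 0.312) and developmental sarcomere genes in 13 of 22 with 4 higher (-0.16, 0.00087, 0.290), the fast and the slow list each having 1 gene higher. Neuromuscular junction genes were lower in 8 of 17 cases and higher in 5 (-0.10, 0.0322, 0.351). Myh1 differed by -0.87 ± 0.04, Myh7b by -0.96 ± 0.06, Klhl41 by -0.80 ± 0.04 and the acetylcholinesterase gene Ache by -1.51 ± 0.09, while Dok7 was higher with FL (0.94 ± 0.04). Myh3 (0.10 ± 0.04, adjusted p = 0.0613, limma) and Tpm3 (0.06 ± 0.04, 0.262) did not pass the test. Myh3 did without dCTD replicate 2 (0.0316) or 3 (0.0215) and with no filter on low values (0.0291).

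The genes that differed most were Lcn2 (9.78 ± 0.24), Slc16a5, a monocarboxylate transporter with 2 counts over the dCTD libraries and a ratio of 399 (interval 110 to 3297), Nags, the enzyme that makes N-acetylglutamate (6.91 ± 0.31), Sgk2 (5.88 ± 0.27), Cidec (5.84 ± 0.37) and Hpdl, a mitochondrial dioxygenase-like gene (5.12 ± 0.07). Hpdl had normalized counts of 71.4 with LacZ, 9312 with FL and 267 with dCTD. At the other end, Serpinb6d was lower with FL than with dCTD (-3.53 ± 0.30), followed by Synpr (-2.65 ± 0.14), Cmya5 (-2.50 ± 0.16), Slc10a4 (-2.42 ± 0.10), Tmprss13 (-2.24 ± 0.24) and Cyfip2 (-2.19 ± 0.06). Cyfip2 and Slc10a4 fell with FL against LacZ (-2.09 ± 0.06 and -2.37 ± 0.10) and did not pass the test with dCTD (0.09 ± 0.05 and 0.05 ± 0.08).

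In total 7059 of 18155 genes differed between FL and dCTD by limma, 3887 higher and 3172 lower with FL, with 589 and 250 of them at least 2-fold and 844 past a minimum change of 1.5-fold. With total-count scaling without Ppargc1a, 3015 were higher and 5324 lower. Adjusted over the list alone, the interferon list had 19 genes higher and 0 lower, complex I 28 and 1, complex IV 10 and 0, ATP synthase 12 and 1, the mitochondrial ribosome 33 and 2, mitochondrial import 23 and 2, fatty acid genes 19 and 4, calcium handling 0 and 14, fast sarcomere 2 and 12, developmental sarcomere 5 and 13 and neuromuscular junction 5 and 9. Extracellular matrix had 14 and 2, p53 and apoptosis 8 and 3 and atrophy and proteolysis 6 and 3. The cytosolic ribosome had 1 and 1, myoblast and reserve cell markers 4 and 4 and brown adipocyte markers 4 and 2. The other lists kept their counts.

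**Figure D3:**
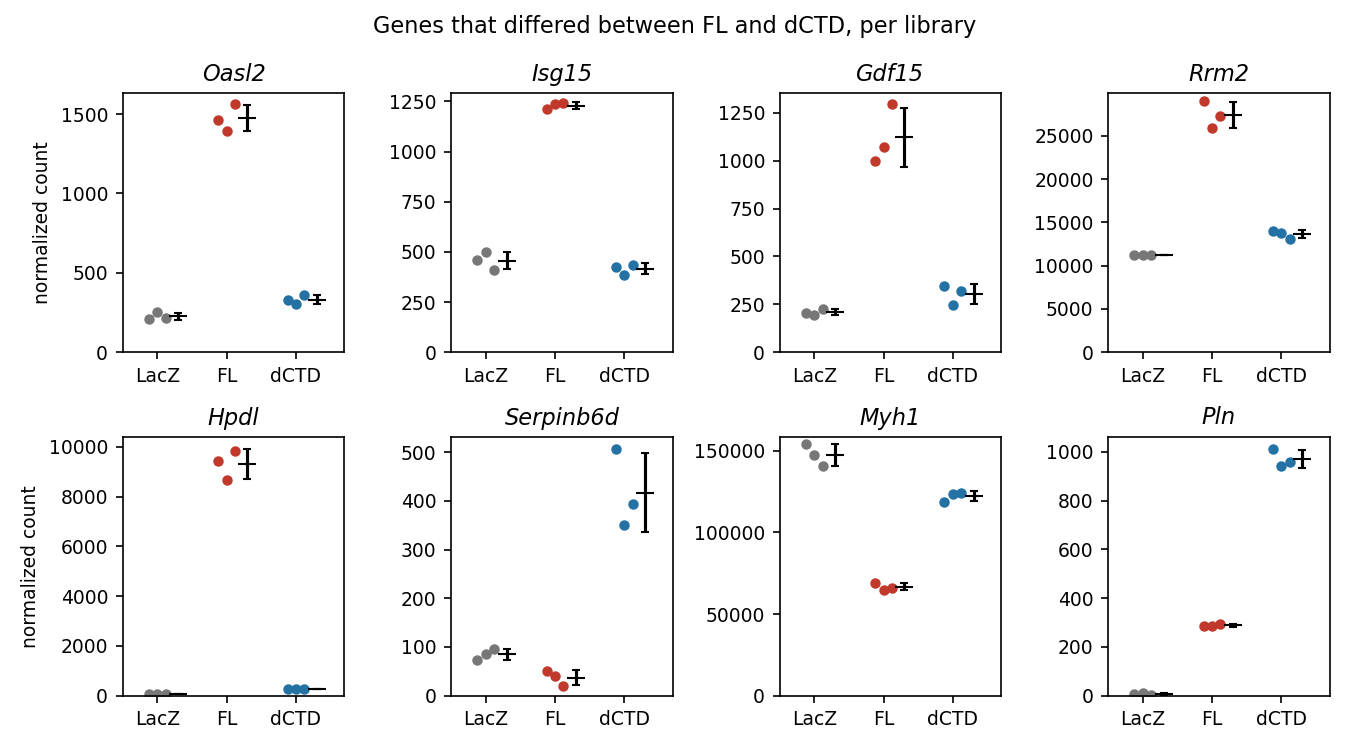
Normalized counts of 8 named genes in each library (points), with the mean and SD of each group of 3, each panel on its own linear axis from 0. Oasl2, Isg15, Gdf15, Rrm2 and Hpdl are highest in the FL libraries, Serpinb6d and Pln are highest in the dCTD libraries, and Myh1 is lowest in the FL libraries.

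The genes that changed with FL had smaller median changes with dCTD. Among the 5409 genes that rose with FL and were tested in all 3 comparisons, the median log2 fold change was 0.51 with FL and 0.25 with dCTD, 50.2% of the FL value. Of these, 3420 (63.2%) also rose with dCTD, 101 fell, and 3196 (59.1%) were higher with FL than with dCTD by the direct test. Among the 5125 genes that fell with FL the medians were -0.32 and -0.19, 60.9% of the FL value, 3217 (62.8%) also fell with dCTD, 119 rose and 2200 (42.9%) were lower with FL than with dCTD. For genes that changed at least 2-fold with FL the shares kept were 61.7% for 1365 genes that rose and 69.6% for 770 that fell. Against LacZ alone, 5637 genes rose with FL, 1576 of them at least 2-fold, so part of them are missing here. The missing genes include Lcn2, Sgk2, Slc16a5, Nags and Cidec, which were too low with LacZ and dCTD to be tested there. Leaving out such genes favours a larger share kept among genes that rose. With total-count scaling without Ppargc1a the shares kept were 56.6% for 4370 genes that rose and 47.7% for 7097 that fell, and 56.8% and 57.6% of them differed toward FL by the direct test. Which direction was kept more therefore depended on the scaling. These genes were chosen by their change with FL, which favours larger FL values.

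Across 17846 genes tested in both comparisons, the log2 fold changes with FL and with dCTD had a Pearson r of 0.862 and a Spearman rho of 0.783, and 80.6% had the same sign. Genes too low to be tested for dCTD against LacZ, such as Lcn2, are not among them. Genes are not independent replicates, and both comparisons share the LacZ libraries. Simulated groups with no change, set against simulated LacZ libraries shared by both, gave a mean r of 0.469 over 100 simulations. The sign was the same in 66.2% of genes. All simulated libraries were drawn from the LacZ means, with genes independent of each other. The covariance was 0.434 against a simulated 0.0108, a difference of 0.424. The 3420 genes that rose in both compare with 1252 for independent lists, and the 3217 that fell in both with 1119, among 17799 genes. With 3 control libraries no split of the controls leaves 2 in each part, so part of the excess of shared calls may come from the shared controls.

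**Figure D4:**
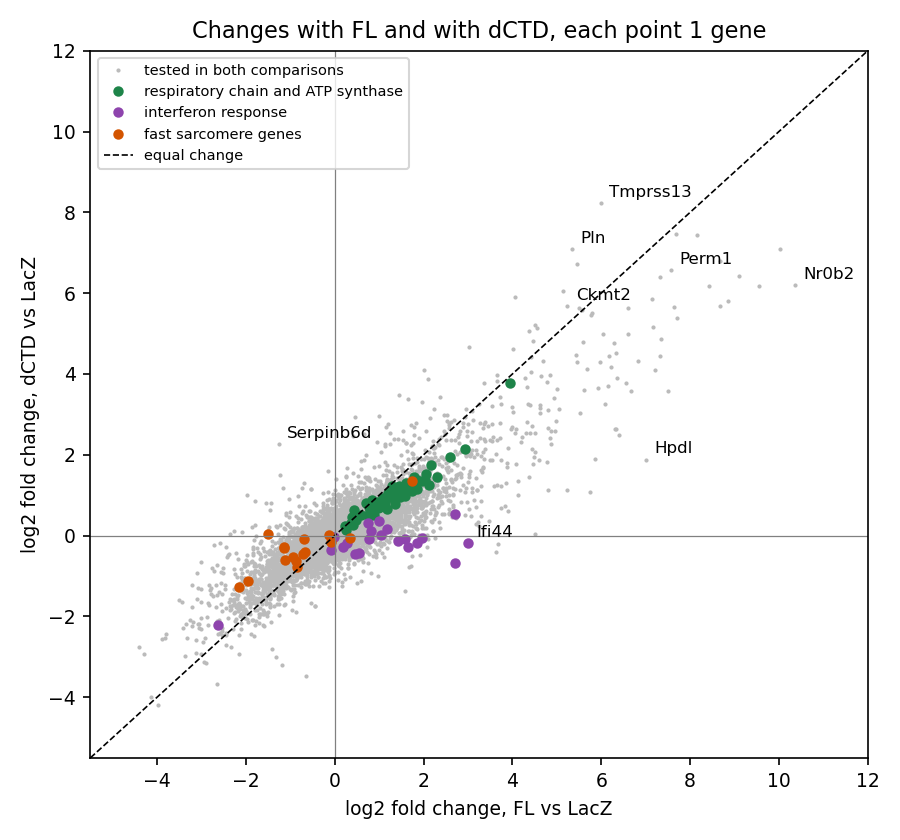
Log2 fold change over LacZ of each gene tested in both comparisons, with FL (horizontal axis) and with dCTD (vertical axis), with the line of equal change dashed. Most respiratory chain genes lie below the line on the rising side, interferon genes lie near 0 for dCTD (median -0.13) and above 0 for FL (median 1.01), and Pln, Tmprss13 and Serpinb6d lie above the line.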

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

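The tests on recovered reads with edgeR and TMM factors, the joint scaling for the LacZ comparisons and total-count scaling with all genes were chosen after seeing the data. So was total-count scaling without Ppargc1a for the lists and for the share of the response kept. The other alternatives were planned. A minimum change of 1.5-fold left 2679 genes for FL against LacZ, 1398 for dCTD against LacZ and 844 for FL against dCTD, because it asks for a larger change. The estimated correlation left 0 lists in each of the 3 comparisons, since it allows for genes of a list moving together. All other alternatives kept the counts of genes within 1.5 times, and no gene called in both reversed its sign. On recovered reads the counts for the 3 comparisons were 11166, 8471 and 7289 with edgeR and TMM factors, 11011, 8423 and 7140 with RLE factors, 11160, 8451 and 7206 with limma-voom, and 10317, 7767 and 6509 with DESeq2. Leaving out 1 library gave 10007 to 10593, 7220 to 7714 and 6027 to 6663 genes, and 23 to 24, 20 to 22 and 20 to 21 lists.

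The share of the FL response kept by dCTD moved by more than its spread between dCTD replicates in these cases. For genes that rose it was 56.6% with total-count scaling without Ppargc1a, 61.7% among genes changed at least 2-fold, 51.3% with edgeR and RLE factors, 51.9% without LacZ replicate 2, 48.4% without FL replicate 2, and 51.9%, 52.4% and 51.5% when genes were called without replicate number 1, 2 or 3 and measured in that number. For genes that fell it was 47.7% with total-count scaling without Ppargc1a, 69.6% among genes changed at least 2-fold, and 70.0% when called without number 2 and measured in number 2. The order of the values for genes that rose and fell therefore depended on the scaling. Leaving out 1 library gave 48.4% to 51.9% for genes that rose, the ends being those cases, and 59.0% to 63.5% for genes that fell.

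The replicate block gave 10720, 7396 and 6732 genes. The numbers did not pair the libraries across all groups. Deviations of same-numbered libraries had correlations from -0.18 to 0.09, and others from -0.18 to 0.15. For 0 libraries was the own number the best match in both other groups. Within a pair of groups it was in some cases, such as replicate 3 of FL and of dCTD (0.09). Lists near the threshold crossed it in a few settings. Endothelial markers for FL against dCTD (adjusted p = 0.0512) passed with the replicate block (0.0464), without FL replicate 3 (0.0316) and without dCTD replicate 2 (0.0396), and extracellular matrix genes (0.0572) without FL replicate 1 (0.0377) and with no filter on low values (0.0088). Among genes named, values that had not passed the test changed sign for Slc10a4 with dCTD (from -0.0312 without LacZ replicate 3 to 0.10 without dCTD replicate 2, and -0.0248 without dCTD replicate 1) and for Tpm3 between FL and dCTD (-0.0071 with total-count scaling without Ppargc1a and -0.0083 with all genes). Myf5 between FL and dCTD, at 0.0016, ranged from -0.0214 without FL replicate 2 to 0.045 without FL replicate 3 and was -0.0656 with total-count scaling without Ppargc1a, -0.0668 with all genes, -0.0090 with edgeR and TMM factors and -0.0095 with limma-voom. Library sizes without the mitochondrially encoded genes were not run, as these are listed at 0. At a depth of 87090490 counts or more, a group with 0 counts allows up to 3, which limits fold changes of silent genes to lower bounds.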

Other observations

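The tests of transgene level and of unfused cells were chosen only after the result was seen. Those of scaling, of transcript length and of other splits of the libraries were set down before it. Some genes responded more to dCTD than to FL, or in the opposite direction. Tnni3 (3.89 ± 0.06 with dCTD and 2.1 ± 0.08 with FL), the cardiac troponin I, and Myl2 (1.67 ± 0.12 and 0.29 ± 0.05), the slow and cardiac regulatory light chain, were higher with dCTD than with FL (limma, adjusted p = 2.1e-07 and 4.3e-05), and Pln showed the same order, with a difference of -1.75 ± 0.17 for FL against dCTD. Asb15, a muscle ubiquitin ligase subunit, rose with dCTD (1.59 ± 0.08) and was at -0.15 ± 0.10 with FL, which did not pass the test except with total-count scaling (-0.24, adjusted p = 0.0464 without Ppargc1a). The rise of Myl2 with FL did not pass by edgeR, by limma-voom or with all 9 libraries scaled together. Serpinb6d rose with dCTD (2.27 ± 0.13) and fell with FL (-1.26 ± 0.28), and Synpr (0.85 ± 0.11 and -1.78 ± 0.17), Myh7b (0.43 ± 0.06 and -0.52 ± 0.06) and Myh8 (0.22 ± 0.04 and -0.60 ± 0.04) did likewise. Tnni3, Myl2 and Asb15 were chosen after their values were seen.

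Among lists not described above, glycolysis and lactate genes were higher with FL than with dCTD in 11 of 25 cases and lower in 5 (median 0.15, camera adjusted p = 0.0171, 0.595 with an estimated correlation), and antioxidant genes in 9 of 20 with 4 lower (0.06, 0.0238, 0.418). Adipocyte markers were higher in 4 of 7 cases (0.28, 0.0071, 0.312). The angiogenic list had 4 of 15 higher and 4 lower (adjusted p = 0.925), including Vegfb (0.83 ± 0.05) and Vegfd (-0.97 ± 0.07). The splicing list had 1 of 29 higher and 2 lower between FL and dCTD (0.725), with Rbm39 at 0.21 ± 0.04 and Clk1 at -0.15 ± 0.04. These are transcript levels, and neither RNA binding nor splicing was tested here. Extracellular matrix genes were higher in 12 of 24 cases and lower in 2 (0.0572), and endothelial markers were lower in 3 of 7 (0.0512). The lists named neither here nor above for FL against dCTD did not pass.

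For 1249 of the 7059 genes that differed between FL and dCTD (17.7%), the level with dCTD lay outside the range from LacZ to FL, 789 above and 460 below it, and 220 of them changed in opposite directions. If dCTD were only a weaker dose of FL, with each gene rising or falling steadily with dose, at most 5% of the calls (353 genes) were allowed, so the 1249 genes argue against that for this set. That limit covers false calls between FL and dCTD only. False calls of dCTD against LacZ could add genes, and the same dCTD libraries enter both tests, so 353 is not a strict ceiling. Total-count scaling without Ppargc1a gave 1366 such genes, 1018 of them the same, which argues against scaling as the source. A response that turns with dose was not tested, nor were other differences between the viruses. For the genes whose level with dCTD lay between LacZ and FL, a difference in transgene level and the missing domain cannot be told apart, because the ratio of Ppargc1a counts, 1.88, goes with the group, and the part of it due to the shorter transcript was not tested.

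Interferon, stress and proliferation genes were higher with FL than with dCTD. A larger share of unfused cells with FL would raise the myoblast and reserve cell markers with the proliferating cell markers, and their medians were -0.01 and 0.48, a difference of 0.49 (95% bootstrap interval 0.23 to 0.58, 10000 resamples of genes). That interval treats genes as independent, and the myoblast and reserve cell markers went both ways, with Sdc4 (0.39 ± 0.04) and Met (0.26 ± 0.04) higher with FL. Some were abundant with LacZ, such as Itga7 with a normalized count of 123829, which would hide a modest share of unfused cells. Myf5, at 1496 with LacZ, was at 0.0016 ± 0.0486 between FL and dCTD, which goes against more unfused cells with FL, though 1 gene does not decide it. Unfused cells and a change within the myotubes therefore cannot be told apart for the proliferation genes. For the interferon and stress genes a possible difference in transgene level and the missing domain cannot be told apart, since the Ppargc1a counts of the FL and dCTD libraries did not overlap. Other differences between the viruses cannot be told apart from these either. A candidate hypothesis is that these genes need the C-terminal domain. Cultures matched for transgene level would test it against that level, but would not remove other differences between the viruses.

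The respiratory chain and mitochondrial ribosome genes are short, so a length bias could raise them together. Against genes of like exonic length, in 20 length bins, the median of the 127 members was 1.13 (quartiles 0.71 and 1.46) for FL against LacZ, while the medians of the bins ranged from -0.04 to 0.04. The cytosolic ribosome genes had a median of -0.02. These values argue against length. Lengths came from a reference annotation, with a value for 99.9% of tested genes.

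Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05, and the real split, 1 of the 10, gave the most genes and lists in every comparison. The real splits gave 10799, 8094 and 7059 genes by limma, and the highest of the other splits gave 0 in each comparison. At an unadjusted p under 0.05 the other splits gave 88 to 217, 95 to 345 and 289 to 607 genes. The other splits put libraries of both viruses on each side, so the difference between viruses adds to the spread within a side. Few calls are therefore built into these splits, and their 0 is no baseline for calls without a virus effect. For the lists, with the preset correlation, the real splits gave 23, 21 and 20 and the highest others 21, 18 and 19. In each mixed split the sides hold unequal numbers of libraries of each virus. Part of the difference between viruses therefore remains between the sides, and lists that move with the virus can pass there. The list counts of mixed splits are thus no baseline either, and their nearness to the real counts does not decide whether the lists moved.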
